A study of Mus musculus with 4 samples.

How the data were processed

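The data were 4 libraries from 10-week-old male C57BL/6J mice: RPF and RNA from heart, and RPF and RNA from tibialis anterior. Per the labels' protocols, 1 lysate of frozen tissue made in cycloheximide was split, total RNA was taken from the crude lysate and depleted of ribosomal RNA, and the rest was digested with RNase I and pelleted by ultracentrifugation without a clearing spin before short fragments were isolated from a gel. RPF reads were mapped to RefSeq transcripts, per the labels, and Bowtie and the mouse build mm9 are named in the submitters' processing notes. The Bowtie version, trimming, and the treatment of reads that map to several places are not given in the sources used here.

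The deposited values are RPM (reads scaled to a fixed library total), per the file headers, for the coding sequence, 5-prime UTR and 3-prime UTR of 1 transcript model per gene, beside the length of each part. The coding columns summed to between 993831 and 998118, so the values are relative to coding reads, and the values were not divided by length. Titin was listed on a composite model of its exons. Every listed gene was above 0 in both coding columns, and no listed gene had fewer than 19 reads in a library over its 3 parts. The rule by which genes were listed is not given in the sources used here, so an unlisted gene is not a 0. No coordinates are given, since the reference used here is of another build than mm9.

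Low values were tested for whole multiples of a single step, the worth of 1 read. In each library 100% of the low values lay within 0.005 RPM, the rounding of the files, of a whole number of reads (13614 to 16666 values tried). The step was 0.0354 RPM in heart RPF, 0.107 in heart RNA, 0.035 in TA RPF and 0.0621 in TA RNA, so 1 RPM was 28, 9, 29 and 16 reads. A rounding of 0.005 is a sizeable part of the RPF steps, so RPF reads are less sure than RNA reads. Exact intervals of ratios were computed from these reads at 95% (conditional Clopper-Pearson) and Wilson intervals for shares. They cover counting error only. No count test could be fitted to the recovered reads, because 1 library per group leaves no residual degrees of freedom.

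Symbols listed on more than 1 row (5 in heart, 4 in TA) were represented by the row with the highest summed coding value. The design had assumed a length-normalized scale. The values were RPM instead, so the same pseudocount and minimum were applied to RPM and list shares are shares of reads. Translational efficiency was log2 of (RPF + 0.1) over (RNA + 0.1), minus its median over genes with at least 1 RPM of RNA in that tissue. Tissues were compared as log2 of (heart + 0.1) over (TA + 0.1) for genes with mean RNA of at least 1 RPM, not centred, and efficiencies by the difference of the centred values for genes with at least 1 RPM of RNA in both. Fold values are on this scale and understate changes of low genes. With no replicates the rule was a size of at least 2-fold. The 2 tissues' tables were made separately by the authors.

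Before the data were examined, 28 gene groups and 11 marker lists, the comparisons, the named genes and most alternatives were fixed. Named genes were, for each of 5 comparisons, the 5 highest and 5 lowest at 10 or more RPM of RNA, Ttn, and for each list the 2 highest, 2 lowest and most abundant members. Some genes that this rule names are not reported here. A list with at least 5 measured members was described by the percentile of its median among 10000 random lists of the same size matched on mean expression in 20 bins, a description of these libraries and not a test. Expression here was the mean log2 level over the libraries that entered the comparison. For efficiencies it therefore included RPF as well as RNA and was not a match on RNA alone. Under another pseudocount, minimum or choice of rows 2000 random lists were drawn. Mitochondrially encoded genes had no listed member.

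The computations were tested on simulated data in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with plots in matplotlib 3.10.9. In libraries drawn from the same proportions at the real depths, 98.5% of 200 genes changed 3-fold in efficiency between heart and TA met the 2-fold rule and 23 unchanged genes of 9796 in that run did so from counting alone. For RNA the values were 98.0% and 12. Of genes changed exactly 2-fold, 48.7% met the rule in efficiency and 44.2% in RNA. Both tissues were drawn at the mean of their levels. Genes low in only 1 tissue were therefore simulated above their level there, and the numbers passing from counting alone may be too low. Of 200 unshifted random lists, 2.5% lay outside the 2.5th to 97.5th percentile. Genes were put into bins at random in that run, so it did not check the matching on expression. Alternatives changed the pseudocount (1 or 0.01), the minimum (5 RPM or none), the choice of rows, the centring, and the scale without the 50 most abundant genes. Removal of the trend with coding length, lists matched on coding length, subtraction of a shared low level of TA reads, and the requirement that the counting interval lie wholly past 2-fold were added after the data were seen.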

Results

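Ribosome-protected fragments (RPF), the short pieces of mRNA that a translating ribosome shields from nuclease, and total RNA were sequenced from mouse heart and from tibialis anterior (TA), a fast hindlimb muscle. Each tissue had 1 RPF library and 1 RNA library, so there were 4 libraries in all and no replicates. The mice were 10-week-old C57BL/6J males. Values were RPM, reads on a coding sequence relative to all coding reads of the library. The steps between low values gave library depths of 28230000 coding reads in heart RPF, 9340000 in heart RNA, 28570000 in TA RPF and 16100000 in TA RNA. In heart 10791 gene symbols were listed and in TA 10352, with 9906 in both. Because no group had a second library, no difference described here has a replicate check and no p-value is given. Intervals are 95% and cover counting error only. Genes are named as higher or lower by a fixed rule of at least 2-fold.

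The series title names titin, the giant sarcomere protein, and the first question was how much of each library its gene took up and how its ribosome occupancy compared with its RNA. Ttn was the most abundant mRNA by reads in both tissues. It took 8.87% of coding RNA reads in heart (Wilson interval 8.85 to 8.89%) and 14.4% in TA (14.4 to 14.4%). It took a smaller share of RPF, 2.25% in heart (2.24 to 2.25%) and 5.23% in TA (5.22 to 5.24%), where it ranked 5 and 3. The ratio of RPF to RNA of Ttn was 0.254 in heart and 0.363 in TA, against medians over genes of 0.737 and 0.835. Relative to those medians the efficiency of Ttn was 0.345-fold in heart (0.344 to 0.346) and 0.435-fold in TA (0.434 to 0.436), or log2 -1.54 and -1.20. That placed Ttn at percentile 8.7 of 10680 genes in heart and percentile 14.8 of 10029 genes in TA. Reads accumulate with length, and the Ttn model was 102942 nt of coding sequence: per kilobase its RNA ranked 97 in heart and 34 in TA. Across genes, efficiency was lower for longer coding sequences (Spearman rho -0.39 in heart and -0.35 in TA, genes not being independent replicates). After the trend with coding length was removed, Ttn stood at -0.20 in heart and 0.04 in TA, so its sign in TA turned, and no other gene was near it in length.

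**Figure D1:**
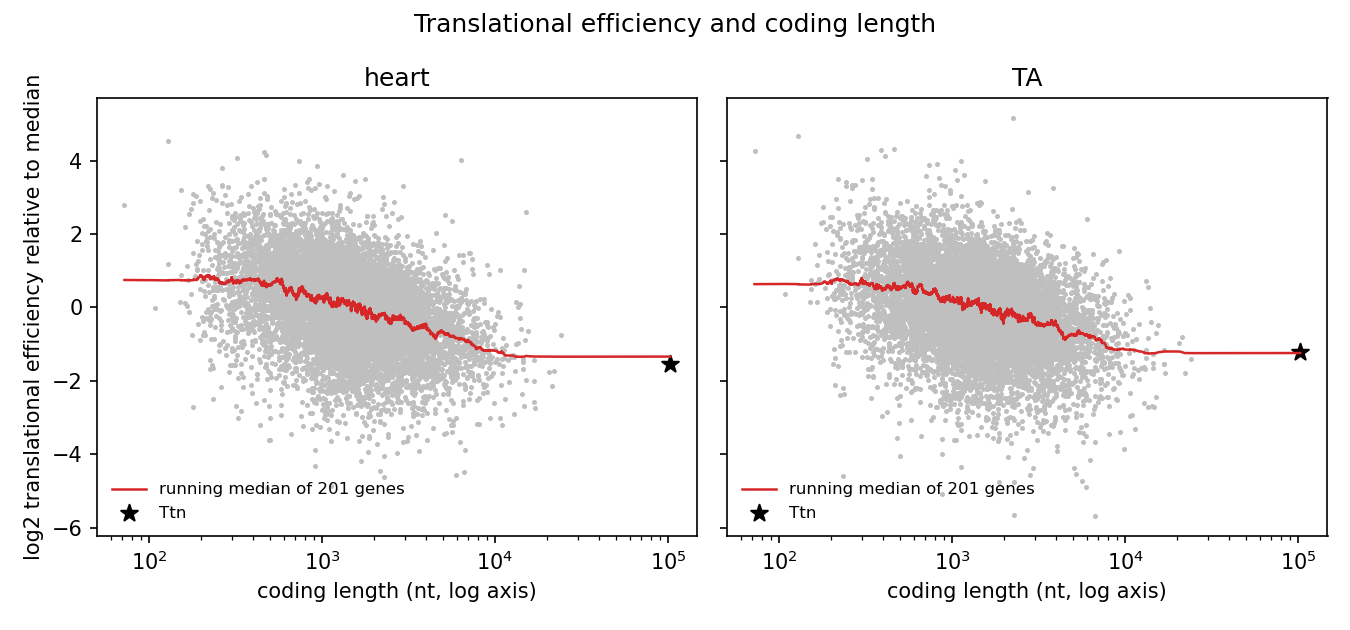
Log2 translational efficiency of each gene (grey points, vertical axis, relative to the median of the tissue) against its coding length in nt on a log axis, in the heart and TA libraries, with a running median across genes (red line) and Ttn (star). The running median declines with length, and Ttn, at -1.54 in heart and -1.20 in TA, lies close to its end.

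In heart, translational efficiency, the ratio of RPF to RNA of a gene relative to the median gene, was high for mRNAs of cardiac contraction, oxidative phosphorylation and glycolysis, and low for giant proteins and for mRNAs with regulatory upstream reading frames. All 8 measured cardiac contractile mRNAs were above the median and 5 were at least 2-fold above it, with a list median of log2 1.27 that lay at percentile 98.3 of random lists matched on expression. Myl3, a ventricular myosin light chain, stood at 2.41, Tnnt2, cardiac troponin T, at 1.81, and Myh6, the main adult cardiac myosin heavy chain, at 1.01. Of 76 oxidative phosphorylation mRNAs, 34 were at least 2-fold above the median and none was 2-fold below (median 0.92, percentile 100), with Uqcrh at 3.29 and Ndufc1 at 3.23. Their coding sequences were short, and random lists matched on coding length had a median of 0.57, against which the list lay at percentile 99.21. Glycolytic mRNAs had a median of 0.88 (percentile 98.18; 10 of 22 at least 2-fold above), among them Pkm at 1.85. The tricarboxylic acid cycle list lay within the range of like lists (0.41, percentile 35.46 on expression and 91.42 on coding length). The fatty acid list did so on expression (0.67, percentile 80.7) but lay above lists matched on coding length (98.68). Markers of fibroblasts and of macrophages and leukocytes had medians of 0.80 (percentile 98.0) and 0.70 (percentile 99.36), which came within the range of like lists at a minimum of 5 RPM (96.95 and 96.1). Immediate early mRNAs, which encode short-lived regulators, had a median of 1.06 (percentile 100; 9 of 18 at least 2-fold above), with Klf2 at 2.96, although Fos was at -1.22. The 18 heat shock and chaperone mRNAs were all above the median gene (0.86), led by Hspb7 at 2.31 and Cryab at 1.99, and the list lay at the edge of the range of like lists (percentile 97.53, and 97.25 with a pseudocount of 1).

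At the other end in heart, 10 of 17 mRNAs with regulatory upstream reading frames were at least 2-fold below the median (list median -1.24, percentile 0.01), including the stress factor Ddit3 at -3.61 and Slc35a4 at -3.25, while 3 were at least 2-fold above it. Of 18 mRNAs of giant sarcomere and cytoskeletal proteins, 10 were at least 2-fold below the median and none was 2-fold above (-1.41, percentile 0.0 on expression and 0.74 on coding length), with Ahnak at -2.74 and Xirp2 at -2.60. With the length trend removed this median was -0.21. The list had a median coding length of 12088.5 nt, and length was matched in 20 bins, which are too coarse for mRNAs this long. The coding length percentile therefore cannot show that these mRNAs were low for their length. Cytosolic ribosomal protein mRNAs centred on the median gene (0.00) but lay low among lists of like expression (percentile 1.0). The 7 fast skeletal contractile mRNAs listed in heart had a median of -1.25 (percentile 0.76; 4 at least 2-fold below), with Mylpf at -1.90 and Tnnt3 at -1.69. The heart RNA of these 2 genes lay at only 0.207 and 0.217% of its TA level. Among the highest single values at 10 or more RPM of RNA were Ywhag (3.97), Mapre3 (3.51), Txnl4a (3.43) and Dynll2 (3.33), and the lowest were Il15 (-4.93), Ccni (-4.86), Prkrir (-4.61), Tcf20 (-4.56) and Gm608 (-4.47). For Ywhag, a 14-3-3 protein, 368 RPM of RPF stood against 31.7 of RNA, and for the cytokine Il15 0.71 stood against 33.4. Over all 10680 genes with at least 1 RPM of RNA, 1710 were at least 2-fold above the median and 1905 at least 2-fold below. Without centring on the median the counts were 852 and 3182. Each gene had 1 transcript model, so reads of other isoforms or of near-identical copies could not be separated.

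In TA, mRNAs of oxidative phosphorylation, glycolysis and the Z-disc, and markers of several cell types other than muscle fibres, had high efficiency. Ribosomal protein mRNAs and those with regulatory upstream reading frames had low efficiency. Efficiency across the 9635 genes measured in both tissues correlated with Pearson r 0.88 (Spearman rho 0.87, across genes). Of genes at least 2-fold above the median, 1010 were shared (1512 in heart and 1460 in TA among these genes, where independent lists would share 229), and of those below, 1324 were shared (1715 and 1804, independent lists 321). Oxidative phosphorylation mRNAs again had a high median (0.85, percentile 100; 31 of 75 at least 2-fold above and 2 below), with Uqcrq at 3.40. Lists matched on coding length had a median of 0.5, and this list lay at percentile 99.54 of them. Z-disc and M-band mRNAs had a median of 0.73 (percentile 99.1; 12 of 28 at least 2-fold above), with Nexn at 2.48 and Myoz2 at -0.87. Fast skeletal contractile mRNAs lay within the range of like lists (0.63, percentile 82.5), from Tnni2, fast troponin I, at 1.32 to Mybpc2 at -0.41, and Myh4, the fast IIb myosin heavy chain, was at 0.63. Atp2a1, the calcium pump of fast fibres, was at 1.24. Immediate early mRNAs had a median of 1.42 (percentile 100), with Klf2 at 2.79 and Junb at 2.13, but the 6 with at least 5 RPM of RNA had one of 0.57, within the range of like lists (percentile 83.55). Glycolytic mRNAs had one of 0.82 (percentile 98.77; 8 of 22 at least 2-fold above). The 18 heat shock and chaperone mRNAs were again all above the median gene (0.86, percentile 99.52, and 99.4 at a minimum of 5 RPM). Medians were also high for markers of macrophages and leukocytes (1.26, percentile 100), endothelium (1.05, percentile 99.97), fibroblasts (0.96, percentile 99.6) and smooth muscle and pericytes (0.92, percentile 99.0). Adipocyte and satellite cell markers lay within the range of like lists (0.72 and 0.45, percentiles 89.68 and 89.2). Of shorter lists, 2 of 3 erythroid mRNAs were at least 2-fold below the median. All 4 nerve, 3 cartilage, tendon and skin and 2 atrial mRNAs were at least 2-fold above it. The 7 cardiac contractile mRNAs listed in TA, whose list took 0.0249% of TA RNA, had a median of 1.94 (percentile 100; 5 at least 2-fold above). Several lay near the minimum, with TA RNA of 2.05 RPM for Mybpc3, 2.36 for Tnni3 and 3.29 for Tnnt2. At a minimum of 5 RPM too few members were left for a percentile.

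Of 69 cytosolic ribosomal protein mRNAs in TA, 25 were at least 2-fold below the median and 3 at least 2-fold above (median -0.69, percentile 0.0), from Rps12 at -2.96 to Rpl41 at 4.25. The upstream reading frame list was again low (-1.62, percentile 0.0; 9 of 15 at least 2-fold below), with Slc35a4 and Ppp1r15a both at -2.66. Giant protein mRNAs had a median of -0.96 (percentile 0.01), but among lists matched on coding length this was percentile 33.8, and with the length trend removed it was 0.24. The highest single values were Khsrp (5.16), Rpl41 (4.25), Ywhag (3.88), Ptrf (3.61) and Mapre3 (3.54), and the lowest were Gm608 (-5.67), Prkrir (-5.64), Tcf20 (-4.89), Asnsd1 (-4.76) and Satb1 (-4.75). Over 10029 genes, 1548 were at least 2-fold above the median and 1878 at least 2-fold below, and without centring 1022 were above.

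**Figure D2:**
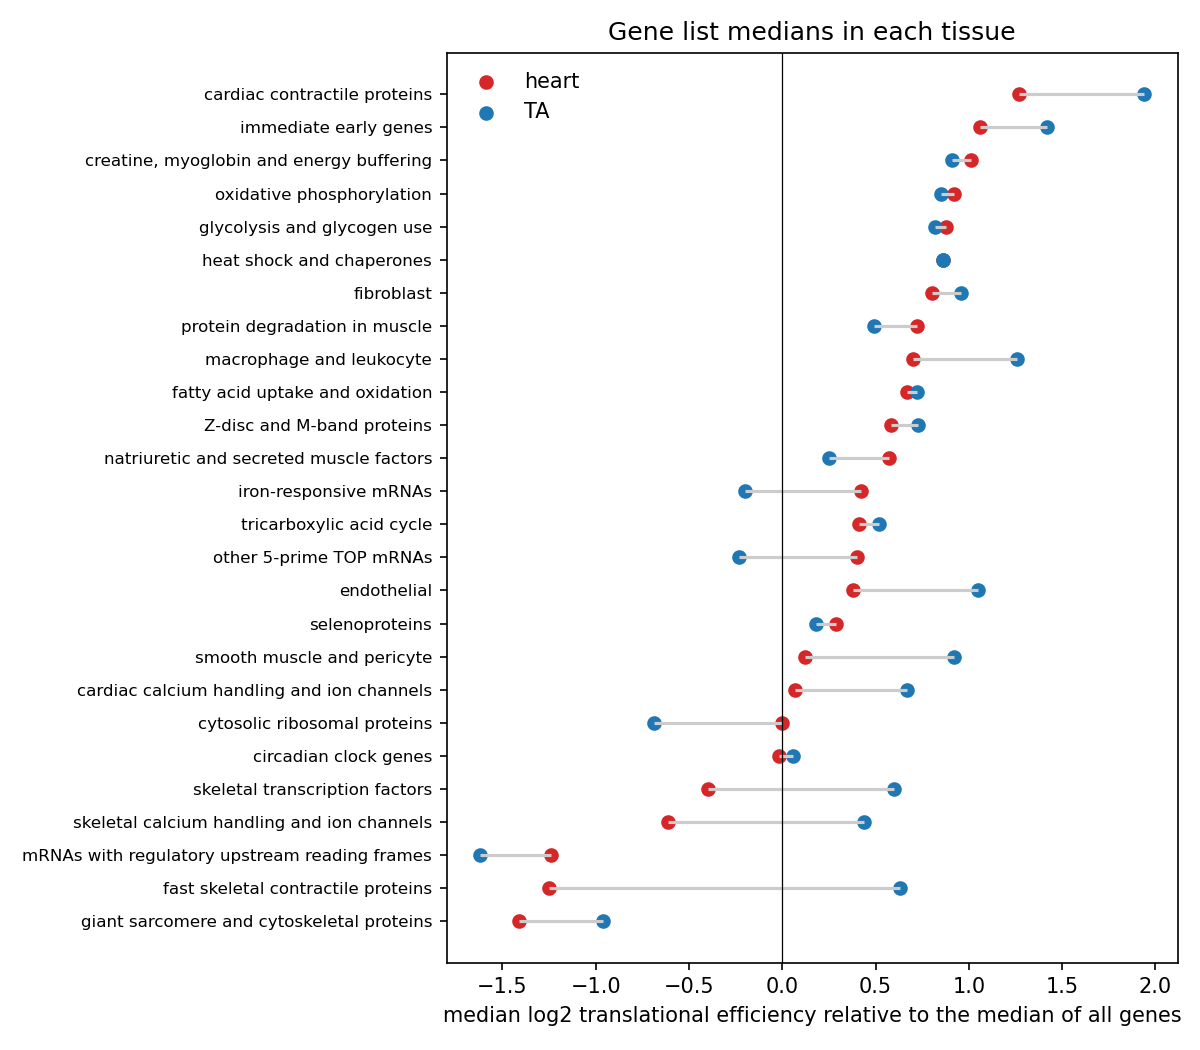
Median log2 translational efficiency of 26 gene lists with at least 5 measured members in each tissue, relative to the median of all genes, in heart (red) and TA (blue), 1 RPF and 1 RNA library per tissue. The upstream reading frame list is low in both tissues (-1.24 and -1.62), and ribosomal protein mRNAs are at 0.00 in heart and -0.69 in TA.

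Heart and TA RNA differed in the genes of contraction, calcium handling and fuel use. The 7 cardiac contractile mRNAs listed for both tissues were all at least 2-fold higher in heart, with a median log2 ratio of 10.02. Mybpc3, cardiac myosin binding protein C, had 5296 RPM in heart and 2.05 in TA (log2 11.27, interval 10.85 to 11.87), and Tnni3, cardiac troponin I, had 4119 and 2.36. Dsp, a desmosome protein, was at 10.57, Tnnt2 at 10.50 and Fhl2 at 10.20. The 7 fast skeletal contractile mRNAs listed in both were all at least 2-fold lower in heart (median -8.61), with Mylpf, the fast regulatory light chain, at -8.91 and Tnnt3, Tnnc2 and Tnni2 at -8.85, -8.81 and -8.61. Atp2a1 was at -8.90, with 69.0 RPM in heart and 32953 in TA, whereas Atp2a2, the cardiac calcium pump, and its regulator Pln were at 8.59 and 8.60. Of 12 cardiac calcium handling and ion channel mRNAs, 8 were at least 2-fold higher in heart (median 3.74), and of 8 skeletal ones 7 were at least 2-fold lower (-3.97). Myh6, Ryr2, Nppa, Gata4 and Nkx2-5 were listed for heart alone and Myh4, Myh1, Myh2, Actn3, Ryr1 and Myod1 for TA alone, but an unlisted gene is not one with a value of 0. Of these, Gata4, Nkx2-5, Myh1, Myh2, Actn3 and Myod1 were chosen after their values were seen.

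The fuel genes separated in opposite directions. Of 22 fatty acid uptake and oxidation mRNAs, 19 were at least 2-fold higher in heart (median 2.28, percentile 100), led by Lpl, lipoprotein lipase, at 4.12 and Ech1 at 3.36. All 75 oxidative phosphorylation mRNAs were above 0 and 38 were at least 2-fold higher in heart (median 1.00, percentile 99.99), as were 13 of 19 tricarboxylic acid cycle mRNAs (1.14, percentile 99.3 on expression and at the upper bound of the range on coding length), with Idh2 at 3.75. Of 22 glycolysis and glycogen mRNAs, 15 were at least 2-fold lower in heart and 1 was higher (median -1.58, percentile 0.0), with Phka1 at -3.88, Phkg1 at -3.53 and Aldoa at -2.61, and the muscle creatine kinase Ckm was at -3.05. Heat shock and chaperone mRNAs had a median of 1.09 (percentile 98.9), with Hspb7 at 3.82 and Cryab at 2.49. The homeodomain protein Hopx was at 6.84 and Ankrd1 at 6.21. Cardiac transcription factors had a median of 2.75 (4 of 6 at least 2-fold higher) and skeletal ones of -2.17 (4 of 5 at least 2-fold lower). Markers of cells other than muscle fibres were also higher in heart: 14 of 15 endothelial mRNAs (median 1.80) and 16 of 16 macrophage and leukocyte mRNAs (2.01) were at least 2-fold higher, with Kdr at 2.75 and C1qa at 2.83. Of 10 smooth muscle and pericyte mRNAs, 7 were at least 2-fold higher (1.16, percentile 98.1 on expression and 92.31 on coding length). Of 17 fibroblast mRNAs, 4 were (0.59, under the shift of the median gene), and Hbb-b1, a red cell globin, was at 4.74.

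Over 9843 genes, 3448 had RNA at least 2-fold higher in heart and 382 at least 2-fold lower. The median gene was 0.70 higher in heart on the log2 scale, and the 50 most abundant genes took 58.1% of coding RNA reads in TA and 36.8% in heart. Centred on that median, 1332 genes were higher and 1026 lower, and the median of the fatty acid list was 1.58, of oxidative phosphorylation 0.31, of the tricarboxylic acid cycle 0.44 and of endothelial markers 1.10.

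RPF also differed between the tissues in the genes of contraction, calcium handling and fuel use. The log2 heart to TA ratios of RPF and RNA correlated with Pearson r 0.88 (Spearman rho 0.79) across 9843 genes. Cardiac contractile genes were again all at least 2-fold higher in heart (7 of 7, median 8.26), and fast skeletal contractile genes all lower (7 of 7, median -10.71). Tnni3 had 9501 RPM of RPF in heart and 1.68 in TA (log2 12.38, interval 12.06 to 12.91). Dsp was at 11.18, Pln at 10.88, Fhl2 at 10.49 and Myl2, the ventricular regulatory light chain, at 10.39. The lowest ratios were those of the calcium buffer Pvalb (-11.83), Tnnt3 (-11.53), Tnnc2 (-11.49), Atp2a1 (-11.40) and Mylpf (-11.14). Fatty acid genes had a median of 2.13 (20 of 22 at least 2-fold higher), oxidative phosphorylation 0.95 (35 of 75) and glycolysis -1.58 (16 of 22 at least 2-fold lower). The tricarboxylic acid cycle list, unlike in RNA, lay within the range of like lists (0.86, percentile 82.64; 9 of 19 at least 2-fold higher). Cardiac calcium handling and ion channel genes had one of 3.54 (8 of 12 at least 2-fold higher) and skeletal ones of -4.40 (7 of 8 at least 2-fold lower). Ribosomal protein genes had a median RPF ratio of 0.88 (28 of 68 at least 2-fold higher, percentile 99.98), with Rpl13a at 2.59, against 0.48 in RNA (2 of 68, percentile 19.48), which was under the RNA shift of the median gene. Centred on the median gene the RPF median was 0.28. The contractile lists took large shares of RPF: the cardiac list 17.2% of heart RPF and 10.2% of heart RNA (Wilson intervals 17.2 to 17.2% and 10.2 to 10.2%), and the fast skeletal list 26.2% of TA RPF and 19.5% of TA RNA. Giant protein genes took 3.33% of heart RPF and 12.2% of heart RNA, and 7.94% and 21.2% in TA.

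In total 2960 genes had RPF at least 2-fold higher in heart and 498 at least 2-fold lower, with 2264 and 309 of these also past 2-fold in RNA (independent lists would share 1037 and 19.3). The median RPF ratio was log2 0.60, and centred on it 1176 genes were higher and 1185 lower.

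**Figure D3:**
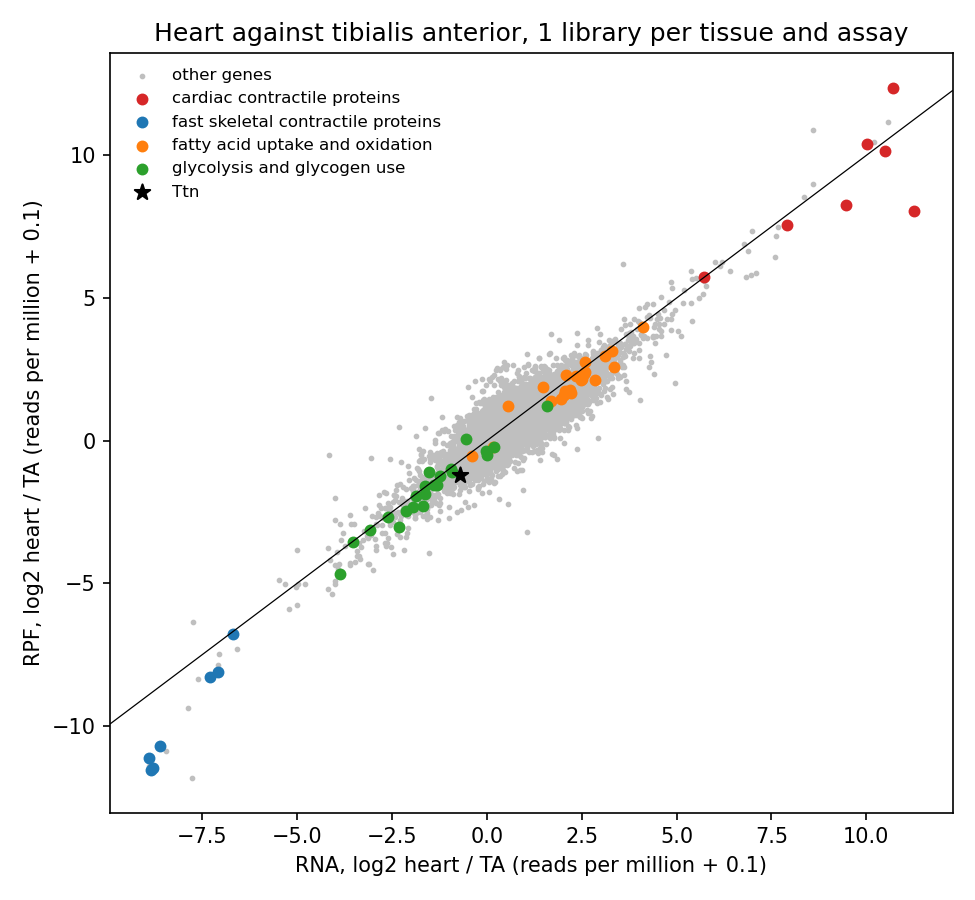
Log2 ratio of heart to TA for RNA (horizontal axis) and RPF (vertical axis), from RPM plus 0.1, 1 library per tissue and assay; grey points are other genes, coloured points are 4 gene lists, the star is Ttn and the line marks equal ratios. Cardiac contractile genes have a median RNA ratio of 10.02 and fast skeletal contractile genes one of -8.61.

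The difference in translational efficiency between the tissues was under 2-fold for 9018 of 9635 genes. Ribosomal protein mRNAs had a higher relative efficiency in heart, and fast skeletal contractile mRNAs and markers of several cell types other than muscle fibres a lower one. Of 68 ribosomal protein mRNAs, 60 had a higher relative efficiency in heart, and 16 of them at least 2-fold (median 0.57, percentile 100 also among lists matched on coding length), with Rpl13a at 2.34 and Rpl38 at 1.81, while Rpl41 was at -1.45. The other mRNAs with a 5-prime TOP motif, a pyrimidine start shared with ribosomal protein mRNAs, had a median of 0.24 (percentile 96.7; 15 of 20 above 0), with Eef1b2 at 1.08. All 7 iron-responsive mRNAs were above 0 (median 0.57, percentile 99.5), with the ferritin chain Fth1 at 1.40 and the iron exporter Slc40a1 at 1.28. In the opposite direction, 4 of 7 fast skeletal contractile mRNAs were at least 2-fold lower in heart (median -1.92, percentile 0.0), and 15 of 15 endothelial mRNAs were below 0 (median -0.60, percentile 0.01), as were 15 of 16 macrophage and leukocyte mRNAs (-0.57, percentile 0.0) and 9 of 10 smooth muscle and pericyte mRNAs (-0.61, percentile 0.0). In these 3 marker lists 0, 4 and 1 mRNAs passed 2-fold, and the RNA of all 3 was higher in heart. Kdr was at -0.95, Csf1r at -1.16 and Rgs5 at -1.42. Giant protein mRNAs had a median of -0.26 (percentile 0.71 on expression and 2.12 on coding length; 10 of 16 below 0). The coding length percentile has the same limit of coarse length bins as that of this list in heart efficiency. Fibroblast markers (-0.23, percentile 1.94; 15 of 17 below 0) and skeletal calcium handling and ion channel mRNAs (-0.34, percentile 0.98; 5 of 8 below 0) lay low on expression but within the range of lists matched on coding length (percentiles 3.6 and 3.68). Glycolysis, fatty acid and tricarboxylic acid cycle mRNAs had medians of -0.03, -0.08 and 0.02, with no member past 2-fold. Oxidative phosphorylation mRNAs had a median of 0.17 (percentile 99.64 on expression; 6 of 75 at least 2-fold higher), which was within the range of lists matched on coding length (92.62) and was -0.01 without centring.

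Among genes with at least 10 RPM of RNA in both tissues, Mef2c, a muscle transcription factor, had the largest value in heart's favour (2.97, counting SE 0.09): its RNA was 43.2 RPM in heart and 215 in TA, and its RPF 80.6 and 57.9. Ankrd23 (2.62), Mapkapk5 (2.47), Rpl13a (2.34) and Chchd3 (2.31) followed, and Pln, which restrains the cardiac calcium pump, was at 2.46 but had only 2.86 RPM of RNA in TA. The RNA-binding protein Khsrp was lowest (-4.08, SE 0.12), with 63.9 RPM of RPF in heart and 591 in TA. Pvalb (-3.86), Tnnt3 (-2.51), Tnnc2 (-2.50) and Atp2a1 (-2.33) came next. The heart RNA of Tnnt3, Tnnc2 and Atp2a1 lay at 0.217, 0.222 and 0.210% of its TA level. With a shared low level of 0.207% of TA reads in RNA and 0.0265% in RPF subtracted from heart, Tnnt3 was at -0.40 and Tnnc2 at -0.83, and Atp2a1 fell under the expression minimum. Pvalb moved the other way, to -7.77, because its own RPF ratio set the level subtracted and left it no RPF in heart. The RNA ratio of Mylpf set the RNA level subtracted, which left Mylpf 0 RPM of RNA in heart, so it dropped out too. Tnnc2 and Tnnt3 kept only 1.03 and 1.31 RPM of heart RNA. Without the genes that dropped out, the medians of the fast skeletal contractile list and the skeletal calcium handling list were -0.39 and -0.10. The levels subtracted came from these same genes, so these medians cannot show whether transfer caused the pattern. Ttn was at -0.34, within 2-fold.

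Among 9635 genes, 392 had an efficiency at least 2-fold higher in heart and 225 at least 2-fold lower. The counts depended on the handling of low values and scale: 241 and 114 genes passed with a minimum of 5 RPM, 226 and 462 without centring, and 118 and 43 when the counting interval had to lie wholly past 2-fold.

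Within a tissue, RPF and RNA of the coding sequence correlated with Pearson r 0.86 in heart (Spearman rho 0.85, 10680 genes) and 0.86 in TA (rho 0.84, 10029 genes) on the log2 scale, across genes, which are not independent replicates.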

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

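The tests on fast skeletal transcripts in this part were chosen after the result was seen, as was the comparison matched on 5-prime UTR length. The test on upstream reading frames was chosen before. Footprints outside coding sequences, which no comparison of the report used, were more frequent in heart: 2.72% of listed RPF reads lay on 5-prime UTRs in heart and 1.34% in TA, and 0.529% and 0.272% on 3-prime UTRs. Relative to coding RPF, the 5-prime UTR value of the median gene was 1.44-fold higher in heart across 2746 genes, against 1.00-fold in RNA across 3042 genes. High ratios of 5-prime UTR to coding RPF stood in Arf6, Romo1 and Rbm24 in heart (390, 366 and 219%) and in St3gal2, Ptp4a2 and Tsc22d4 in TA (533, 342 and 268%), genes chosen after their values were seen. The hypothesis that such footprints mark mRNAs with known regulatory upstream reading frames was tested on the list fixed beforehand. Its median ratio was 20.4% in heart (12 members) and 10.2% in TA (10 members), at percentiles 100.0 and 99.9 of lists matched on RPF level. High percentiles of this kind were not particular to that list. Circadian clock genes lay at 98.73 in heart and 99.33 in TA, and cardiac transcription factors at 99.98 in heart. In TA, skeletal transcription factors lay at 98.57 and endothelial markers at 99.42. Against lists matched on 5-prime UTR length, a comparison added later, the percentiles of the upstream reading frame list were 99.1 in heart and 88.9 in TA. In TA the longer 5-prime UTRs of its mRNAs therefore remain open as a reason. No comparison matched on RPF level and 5-prime UTR length together, or on RNA. The coding efficiency of the list was itself low (median log2 -1.24 in heart and -1.62 in TA), and low coding RPF for the RNA raises this ratio. The percentiles therefore cannot show, in either tissue, that its 5-prime UTRs held more footprints per mRNA.

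Atp2a1 was at least 2-fold above the median efficiency in TA (1.24) and 2-fold below it in heart (-1.09), and Mef2c went the other way (1.34 in heart and -1.63 in TA). The opposite sides of these values drew attention, and neither difference between the tissues was tested, for want of replicates. Mef2c has several isoforms and 1 model was listed.

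Atp2a1 belongs to a pattern: fast skeletal transcripts sat at a low level in the heart libraries. Of 10 genes above 5000 RPM in TA RNA and under 1% of that in heart RNA, 5 (Mylpf, Atp2a1, Tnnt3, Tnnc2 and Tnni2) had heart RNA at 0.207 to 0.255% of TA, close to a common lowest level, as a transfer of TA RNA library reads into the heart RNA library would give; the number of genes asked for was set with these ratios known. Skeletal muscle in the heart lysate would bring RPF and RNA alike, but the RPF ratio divided by the RNA ratio had a median of 0.221 over the 10 genes (0.0586 to 0.940), which argues against it as the whole source. Myh4 and 4 other genes above 5000 RPM in TA RNA were not listed for heart, although transfer at the lowest ratio would put Myh4 at 209 RPM there. That counts against transfer, but the rule by which genes were listed is not given, so transfer stays open. True low expression with little translation in heart also stays open, and either may account for the low heart efficiencies of these genes.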

How the results depend on the processing

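No paired analysis was possible because each group had 1 library. Of the alternative values of results that answer a comparison, 111 stayed within 1.5 times (counts) or within counting error (values), 32 moved and 1 reversed, and the cause was not tested except where the setting's construction shows it. For Pearson r the bound was instead a sampling interval that takes genes as independent, which they are not. Without centring, efficiency counts were 852 higher and 3182 lower in heart (21.1% of calls higher, against 47.3%), 1022 higher in TA (28.7% against 45.2%), and 226 and 462 for the difference between tissues (32.8% against 63.5%). Without the 50 most abundant genes that difference had 368 lower (43.7% higher), and the higher shares of heart and TA efficiency were 30.7% and 36.6%. Centred on the median, RNA gave 1332 and 1026 (56.5% higher against 90.0%) and RPF 1176 and 1185 (49.8% against 85.6%). Without the 50 most abundant genes RNA gave 1578 and 860 (64.7%) and RPF 1355 and 1051 (56.3%). The efficiency difference had 241 and 114 genes at a minimum of 5 RPM, where fewer genes were tested, and 143 lower with a pseudocount of 1. With the counting interval wholly past 2-fold, an alternative added after the data were seen and stricter by construction, 1132 genes were higher in heart efficiency, 1023 in TA efficiency, 2249 in RNA, and 118 and 43 were higher and lower in the efficiency difference. Ttn in heart was -1.58 with a pseudocount of 1, -1.48 at a minimum of 5, -1.98 without centring and -0.20 with the length trend removed; in TA it was -1.24, -1.12, -1.46 and, reversed, 0.041 (0.04 to 2 decimals). With the length trend removed the giant protein median moved from -1.41 to -0.21 in heart and turned to 0.24 in TA. Signs also turned for the circadian clock RNA median (-0.50 when centred and -0.40 without the 50 most abundant genes) and the oxidative phosphorylation efficiency difference (-0.01 without centring). Of 30 list medians of heart efficiency, 13 lay outside the central 95% of like lists, against 9 with a pseudocount of 1, 9 of 27 at a minimum of 5, and 16 with lists matched on coding length, an added alternative. Heat shock mRNAs, fibroblast markers and the erythroid list came within that range in both of the first settings, protein degradation with the pseudocount, and macrophages and leukocytes at the minimum. In TA the immediate early, fatty acid and skeletal transcription factor lists came within it at a minimum of 5 (percentiles 83.55, 97.0 and 89.22). At that minimum the cardiac contractile list in TA had too few members left for a percentile. For the efficiency difference 11 of 26 lay outside and 8 on coding length, without the fibroblast, skeletal calcium handling and oxidative phosphorylation lists. Pearson r of RPF and RNA was 0.833 in heart and 0.816 in TA at a minimum of 5, and 0.865 in TA with a pseudocount of 1. The length trend was likewise an added alternative. Restriction to RefSeq accessions removed Ttn alone, and a denominator without mitochondrial and noncoding entries was not run, since every entry but Ttn had a RefSeq coding accession and no mitochondrially encoded gene was listed. Depth limits low genes: 1 RPM is 9 reads in heart RNA.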

Other observations

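The tests on coding length and the length-matched test of ribosomal protein mRNAs were set before their results were seen, and the test on other TOP mRNAs after. Values of other gene groups are given first. Natriuretic and secreted factors had RNA higher in heart (median 2.32, 5 of 8 at least 2-fold higher), with Angptl4 at 3.04 and Ctgf at 2.68, while their efficiency difference was -0.45 (percentile 1.74, and 7.1 with a pseudocount of 1), with Il15 at -1.37 and Vegfa at 1.07. Among 12 selenoproteins (median RNA 0.62), Sepn1 RNA was 2.58 and Sepw1 RNA -2.76. Protein degradation genes were at -0.01 in RNA, below the median gene (percentile 0.16), with Asb5 at -3.14. Immediate early mRNAs had a median RNA ratio of 1.37 (12 of 17 at least 2-fold higher in heart), with Egr1 at 3.15 but Nr4a1 at -4.19. Circadian clock genes had a median RNA ratio of 0.19, which turned to -0.50 when centred, with Hlf at 1.63 and Nfil3 at -1.36. Creatine, myoglobin and energy buffering genes had one of 1.64, with Ckb at 3.15 and Ckm at -3.05.

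Small lists are given as values. The median RNA ratio was 0.64 for 3 slow skeletal contractile genes, with Mybpc1 at -8.45, 0.89 for 4 histone genes, 4.74 for 2 micropeptide genes and -0.38 for the 1 listed gene of the long noncoding RNA list, which had a RefSeq coding accession. Among markers it was 4.39 for 3 erythroid genes, 0.29 for 4 nerve genes, -2.56 for 1 atrial gene, 1.95 for 2 satellite cell genes and -0.68 for 3 cartilage, tendon and skin genes, while the 1 adipocyte gene, Fabp4, was at least 2-fold higher in heart. Of 7 satellite cell markers, 2 were listed in heart and 6 in TA, and of 9 adipocyte markers 2 and 5. These few values therefore say nothing of cell numbers. The 5 epithelial and mesothelial markers were listed for heart alone, with a median efficiency of 0.82.

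Efficiency was higher for shorter coding sequences in both tissues. Loss of reads at the ends of short coding sequences would leave no trend among long ones, but among coding sequences of at least 1500 nt rho was -0.262 in heart and -0.243 in TA. Low read numbers are argued against by rho of -0.470 and -0.375 among genes with at least 50 RPM of RNA. No biological explanation was tested.

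Ribosomal protein mRNAs had a higher relative efficiency in heart than in TA. Short coding sequences are argued against, since the list lay at percentile 100.0 of lists matched on coding length. A difference shared by all TOP mRNAs is a possible explanation that stays open, because the other TOP mRNAs were at percentile 96.65, short of the upper bound set for it. The tissue itself stays open, as does any difference between the single libraries.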
